A study of Homo sapiens with 4 samples.

How the data were processed

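RNA from SKOV3, an established human ovarian cancer cell line, was sequenced in 2 groups of 2 libraries. The first group was ordinary 2D culture at day 0, and the second was spheroids at day 8 on a plate coated with the siloxane polymer pV4D4 in medium with serum replacement. Poly(A) RNA was isolated after DNase treatment, per the labels' protocols, which name both a directional and a plain version of the library kit, so that the strand information of the libraries is not settled by the labels. The labels do not say that the replicates came from separate cultures. P-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of lists say no more about separate cultures.

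The deposited values are RPKM (reads scaled by exon length in kilobases and by the size of the library), 1 value per RefSeq transcript and library, in 48118 rows with 25689 gene symbols. Per the file header they were made with HOMER from the exons of RefSeq transcripts on hg19, counting the sense strand only, and the column names say FPKM where the command says RPKM. STAR 2.4.0, HOMER and DESeq are named in the submitters' processing notes, and how DESeq was used is not given in the sources used here. The deposited table also holds the exon length and the number of genomic copies of each transcript. The command in the header names 2 further libraries, which were not used here. The spheroid columns are named SR, read as serum replacement, where the sample titles say ssiCSC. They were matched by day and library number. Genes of the HLA region have copies on alternative haplotypes in hg19, and several, HLA-E and TAP1 among them, are listed at 0 in all 4 libraries, so values in that region are uncertain. Values of paralogous genes (histones, ribosomal proteins with pseudogenes, metallothioneins, protocadherins) are likewise uncertain.

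Depth was recovered from the low values, which are whole multiples of 1 read. The estimates were 7.98 M and 11.08 M reads for the 2D libraries and 8.71 M and 10.97 M reads for the spheroid libraries, and 100.0% of the low values used (up to 8 reads) were whole within 0.1 of a read in each library. In a transcript of 1 kb, 1 read was worth 0.125, 0.09, 0.115 and 0.091 RPKM in these libraries. A fold against a group with no reads is a lower bound set at 3 reads over both libraries of the group, and covers counting error only. Because the unit is RPKM, no count test was used for the main result.

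Where several rows carried 1 symbol, the row with the highest mean stood for the gene. Genes with a mean RPKM of at least 1 over the 4 libraries, 11278 in all, were compared as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, 2-sided), with values as deposited and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, spheroid minus 2D, with the standard error (SE), and understate changes of low genes. With 2 libraries against 2, a permutation test of a single gene cannot go below 0.333. On simulated data for this comparison (11250 genes tested), the fit called 95 of 100 genes changed 4-fold and 14 of 100 genes changed 2-fold. It called 9 of 11050 unchanged genes, which were 7.6% of its calls. The simulated libraries shared 1 scale, with a spread taken after median ratio scaling. These figures therefore do not give the error rate of the main result, where the libraries differed in scale.

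Lists of genes were fixed before the data were examined, as were the test, the filter and the rule for named genes. Of 48 lists, 42 had at least 5 tested members and were compared with all other genes by camera, limma's set test, with a preset correlation of 0.01. Its p-values rest on the number of genes and the spread of their statistics, and do not measure replication. The same test with an estimated correlation, and fry, were run beside it, and list medians were set against random lists matched on expression. With the correlation estimated, camera rests on the 2 residual degrees of freedom of these libraries. A list could then hardly pass, so a failure there cannot decide against it. Named genes were the 10 largest rises and 10 largest falls among protein-coding genes past the threshold without overlap of the groups, up to 4 genes with the smallest p of each of the 12 lists with the smallest camera p and of the stem cell, Wnt, epithelial and mesenchymal lists, and 13 genes fixed by name. Genes named outside the rule are given as values, and were chosen after their values were seen. A few genes are not reported here.

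Alternatives were other pseudocounts (0.1 and 0.5), no filter, a minimum of 5 RPKM, median ratio scaling, quantile normalization, rescaling to a fixed sum (TPM), other settings of the empirical Bayes step, the replicate number as a block, other choices of row, and leaving out each library. Cyclic loess normalization, voom on the recovered reads, and median ratio scaling with each library left out were added after the data were seen. Where 1 library of a group is left out, the residual spread rests on the other group's pair alone. A call lost there need not mean a smaller fold change. Scripts for the remaining steps ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Coordinates are those of the deposited table (hg19).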

Results

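SKOV3 cells grown as 8-day spheroids were compared with the same line in 2D culture at day 0, with 2 libraries per group (n = 2 throughout, errors are SD unless named SE). The study's title concerns a method for making spheroids with properties of cancer stem cells from cancer cell lines, and the comparison asks which transcripts differ between both forms of culture. Growth as spheroids, the coated plate, the medium and the day change together here. No difference below can be assigned to 1 of them. The share of reads in listed exons was taken over 1 row per gene symbol, the row with the highest mean. It leaves out exons found only in other rows, and counts exons shared by several symbols for each. It was 42.24% and 41.32% in the 2D libraries and 30.11% and 22.9% in the spheroid libraries. The nuclear RNAs MALAT1 and NEAT1 together took 0.718% and 0.691% of reads in 2D and 2.434% and 2.573% in spheroids.

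In spheroids MMP1, COL6A1, CP, ANGPTL4, LCN2 and SLPI rose, and the receptor gene ERBB2 went from 73.1 ± 9.38 to 299 ± 38.4 RPKM. Genes of the matrix protein thrombospondin 1 (THBS1), the growth regulators CYR61 and CTGF, the receptor AXL and the Wnt inhibitor DKK1 fell. All 28 tested genes of the G2/M phase of the cell cycle fell, MKI67 from 65.2 ± 8.36 to 6.61 ± 4.59 RPKM. Listed genes of the interferon response, of antigen presentation and of ovarian tumours that passed the filter rose more than other genes by camera (adjusted p = 0.568 with an estimated correlation for each of these lists). Of the tested genes fixed as stem cell markers 0 rose with values as deposited, though CD44 did after quantile normalization and cyclic loess, and ALDH1A1, PROM1, SOX2, NANOG and POU5F1 had at most 0.266 RPKM in any library.

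The 10 largest rises were led by MMP1, an interstitial collagenase (NM_002421, chromosome 11, 102660641 to 102668966), with 0.471 ± 0.146 RPKM in 2D and 159 and 28.0 RPKM in the spheroid libraries (log2 fold change 5.54, SE 0.69, adjusted p = 0.003). PPP1R1B, a phosphatase inhibitor, went from 1.25 ± 0.134 to 48.9 ± 25.7 RPKM, and COL6A1, a chain of collagen VI, from 1.33 ± 0.111 to 38.5 ± 22.2. The ferroxidase CP rose from 0.9 to 27.3 ± 3.5 RPKM and ANGPTL4, an inhibitor of lipoprotein lipase, from 1.40 ± 0.113 to 32.1 ± 1.63. CD52, C8orf4, LCN2, DDIT4L and SLPI completed this group, with log2 fold changes of 3.56, 3.28, 3.19, 2.99 and 2.95. LCN2 and C8orf4 differed between the spheroid libraries (47.7 and 11.5 RPKM, and 47.3 and 14.9 RPKM).

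The largest fall was that of THBS1 (chromosome 15, 39873280 to 39889668), from 237 ± 32.9 to 0.26 ± 0.032 RPKM (log2 fold change -7.55, SE 0.30, adjusted p = 0.00019). CYR61 fell from 50.7 ± 2.52 to 0.636 ± 0.166 RPKM, ADAMTS1 from 57.8 ± 11.2 to 1.15 ± 0.466, and EDN1, the precursor of endothelin 1, from 32.0 ± 1.77 to 0.322 ± 0.222. AXL, PLK2, GADD45A, MT2A and CYP24A1 fell by 4.46, 4.38, 4.11, 4.04 and 4.01 on the log2 scale. After median ratio scaling THBS1 had -7.18, and each of these genes kept its direction.

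**Figure D1:**
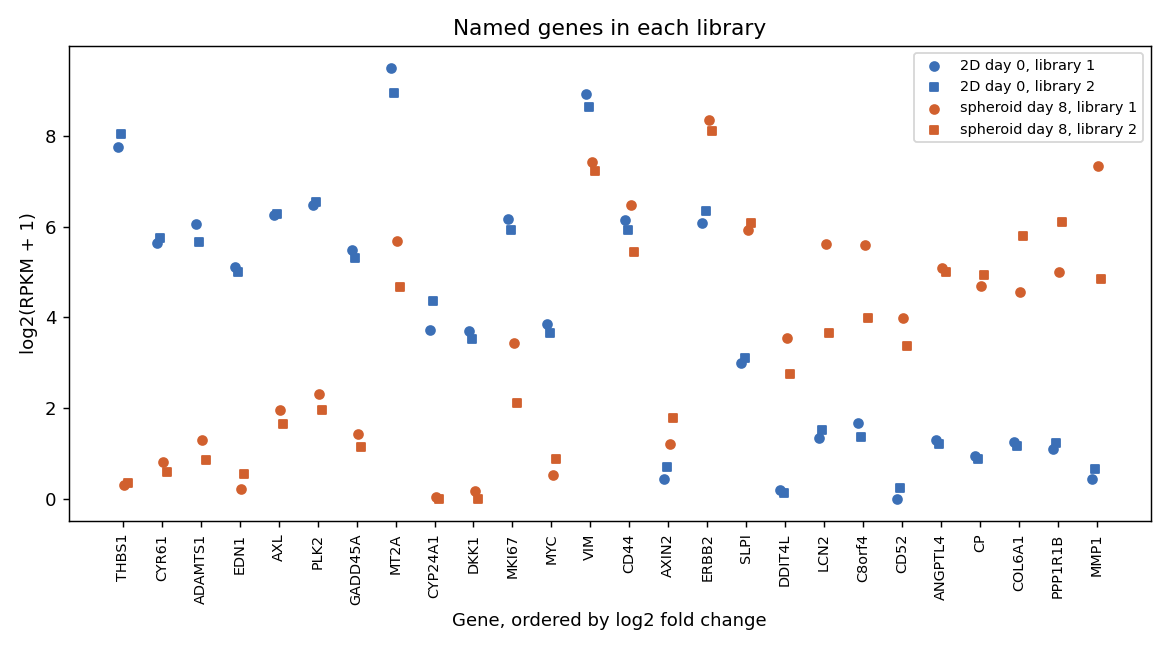
log2(RPKM + 1) of named genes in each library (circles and squares are libraries 1 and 2 of a group, blue for 2D and orange for spheroids), ordered by log2 fold change. THBS1 lies at the left with a log2 fold change of -7.55 and MMP1 at the right with 5.54, where its spheroid libraries lie apart at 159 and 28.0 RPKM.

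Across all genes the balance of higher and lower calls depended on the scale. With values as deposited, 643 genes were higher and 4198 lower in spheroids (13.3% of calls higher). The median log2 fold change of all tested genes was -0.55, so that a gene at -0.55 was at the middle. RPKM is scaled by all reads of a library, and the share of reads in listed exons was lower in spheroids. RPKM summed over genes was 135647 and 132510 in 2D and 87990 and 65702 in spheroids. A call of lower as deposited carries this common fall, and need not mean a fall against other genes. After median ratio scaling 1366 were higher and 2134 lower (39% higher), after quantile normalization 1250 and 1306 (48.9%), after rescaling to a fixed sum 1911 and 1323 (59.1%), after cyclic loess 1504 and 1444 (51%), and by voom 1883 and 2070 (47.6%). The median shift was larger at higher expression, -0.32 for genes of 1 to 5 RPKM and -1.49 for genes of at least 100 RPKM. At 2-fold or more, 381 genes were higher and 2898 lower as deposited, against 753 and 1154 after median ratio scaling. The groups did not overlap in 8986 genes (79.7%) as deposited, a count that the shift of all genes enters, in 8272 (73.3%) after median ratio scaling and in 8047 (71.4%) after cyclic loess. Chance gives 33.3% where genes do not shift together. Without 2D library 1 the counts were 283 higher and 1256 lower, without 2D library 2 they were 403 and 1629, and without spheroid library 1 there were 6574 lower.

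The cell cycle lists fell, and with them a list of histone genes that was fixed as a sign of RNA quality. All 28 G2/M genes fell, adjusted over all genes and adjusted over the list alone (camera adjusted p = 1.04e-09, adjusted p = 0.729 with an estimated correlation). CDC20 fell from 74.9 ± 6.57 to 4.03 ± 1.74 RPKM, PLK1 from 32.4 ± 1.48 to 2.23 ± 1.29, UBE2C from 28.1 ± 2.77 to 3.19 ± 0.69 and CENPE from 13.0 ± 3.37 to 1.37 ± 0.337. All 26 genes of G1/S and DNA replication fell, 26 also when adjusted over the list alone (camera adjusted p = 3.74e-07, adjusted p = 0.729 with an estimated correlation), with CDC45, GINS2, CDT1 and GINS1 down by log2 values of -2.31, -2.59, -2.17 and -2.50. All 17 replication-dependent histone genes, the RNA quality list, fell, 17 adjusted over the list alone (adjusted p = 1.6e-05, adjusted p = 0.729 with an estimated correlation), HIST1H1E, HIST1H2AB, HIST1H1D and HIST1H1B by log2 values of -2.52, -3.01, -1.89 and -2.08. After cyclic loess 28, 24 and 15 genes of these lists fell, and 28, 25 and 16 did as deposited without 2D library 1. With median ratio scaling and without 2D library 1, 0 genes of each list passed, and without 2D library 2, 1 G2/M gene did.

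Genes of protein synthesis fell too, less firmly. All 21 genes of MYC and ribosome biogenesis fell, 21 adjusted over the list alone (camera adjusted p = 2.75e-05, adjusted p = 0.729 with an estimated correlation), 16 after median ratio scaling and 12 after cyclic loess, with RRS1, UTP20 and FBL at log2 fold changes of -2.02, -1.97 and -2.07 and SRM falling from 14.1 ± 0.202 to 2.84 ± 0.745 RPKM. Without 2D library 1 or 2D library 2, 8 and 13 of the 21 fell as deposited, and 0 in either case with median ratio scaling. Of 30 cytosolic ribosomal protein genes 27 fell, and 30 when adjusted over the list alone (adjusted p = 3.08e-05, adjusted p = 0.729 with an estimated correlation). RPS2 fell from 144 ± 10.4 to 27.8 ± 2.64 RPKM, and RPLP0, RPL11 and RPLP1 fell by 2.33, 1.66 and 1.77. After cyclic loess 2 of these 30 fell. Without 2D library 1 or 2D library 2 the count was 1 in either case, and the list's adjusted p was 0.0686 and 0.0688. RPL11 and RPLP1 lost their calls without 2D library 1 (adjusted p = 0.231 and 0.186) and without 2D library 2 (adjusted p = 0.141 and 0.137). RPLP0 lost its call without 2D library 1 (adjusted p = 0.0608), as did RPS2 without 2D library 2 (adjusted p = 0.0523).

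YAP/TAZ targets, genes driven by the effectors of the Hippo pathway, fell in 19 of 23 cases, 19 adjusted over the list alone, and 1 rose (camera adjusted p = 3.76e-05, adjusted p = 0.568 with an estimated correlation). CTGF fell from 15.6 ± 2.41 to 0.039 ± 0.055 RPKM, AMOTL2 from 18.5 ± 1.55 to 0.637 ± 0.055 and TGFB2 from 9.81 ± 0.335 to 0.154 ± 0.086, and the gene that rose was IGFBP3. This call was lost without 2D library 1 (adjusted p = 0.0616) and without 2D library 2 (adjusted p = 0.0882). After median ratio scaling 13 fell and 1 rose, and after cyclic loess 12 and 1. With median ratio scaling, 5 fell without 2D library 1 and 6 without 2D library 2.

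Of 19 tested interferon response genes 9 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.18e-10, adjusted p = 0.568 with an estimated correlation). IFITM1 went from 0.317 ± 0.448 to 7.05 ± 1.78 RPKM, IFI6 from 1.16 ± 0.359 to 5.96 ± 0.592, IFI27 from 0.396 ± 0.205 to 6.53 ± 3.39 and OAS1 from 0.219 ± 0.146 to 2.28 ± 0.506. The gene that fell was HERC5. Its call was lost without 2D library 1 (adjusted p = 0.0942), without 2D library 2 (adjusted p = 0.103) and after median ratio scaling (adjusted p = 0.0511). Of 20 listed antigen presentation genes 8 were tested. Of these 5 rose, 6 adjusted over the list alone (camera adjusted p = 3.74e-07, adjusted p = 0.568 with an estimated correlation). With no filter the list still passed as higher (camera adjusted p = 5.35e-05). The invariant chain gene CD74 was listed at 0 in both 2D libraries and reached 4.35 and 7.02 RPKM in spheroids, at least 53.4-fold higher. HLA-B and HLA-C rose by 2.11 and 1.24 on the log2 scale, with adjusted p of 0.01 and 0.0301, in a region where the haplotype copies of hg19 make values uncertain. HLA-C lost its call without 2D library 1 (adjusted p = 0.242), and both lost theirs without 2D library 2 (adjusted p = 0.138 and 0.404). Leukocyte markers had a median of 0 RPKM in every library, and of them PTPRC, which codes for CD45, was listed at 0 in 2D and had 0.397 and 0.575 RPKM in spheroids. Of the interferon list 6 genes rose without either 2D library, and of the antigen list 3 and 1, while after cyclic loess 12 and 8 rose. With median ratio scaling and without either 2D library, 0 genes of both lists passed.

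Of 18 genes listed as markers of ovarian and Müllerian tumours 7 were tested, and the rest lay below the filter. Of the 7 tested 4 rose, 5 adjusted over the list alone (camera adjusted p = 6e-07, adjusted p = 0.568 with an estimated correlation). With no filter the list still passed as higher (camera adjusted p = 0.00249). WFDC2, which codes for the tumour marker HE4, was listed at 0 in both 2D libraries and had 4.09 and 6.98 RPKM in spheroids, at least 19.7-fold higher. SLPI, a protease inhibitor, went from 7.33 ± 0.451 to 63.5 ± 5.03 RPKM, and ESR1, the oestrogen receptor, from 0.449 ± 0.073 to 1.76 ± 0.124. WFDC2 and ESR1 passed the filter only through their spheroid values. The call of ESR1 was lost without 2D library 1 (adjusted p = 0.0592). PAX8 had 30.6 ± 1.97 and 48.0 ± 3.59 RPKM and did not pass as deposited (adjusted p = 0.148). It passed after median ratio scaling (adjusted p = 0.0192) and without spheroid library 1 or spheroid library 2 (adjusted p = 0.00943 and 0.0306).

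The other lists among the 12 with the smallest p had mixed members. Of 26 lysosome and autophagy genes 5 rose and 2 fell, the same adjusted over the list alone, and 11 rose and 0 fell after median ratio scaling (camera adjusted p = 8.52e-05, adjusted p = 0.729 with an estimated correlation), led by GAA, GABARAPL1, CTSD and GRN with log2 fold changes of 1.85, 1.23, 1.99 and 1.77. The last 3 lost their calls without 2D library 1 (adjusted p = 0.068, 0.173 and 0.168) and without 2D library 2 (adjusted p = 0.162, 0.0632 and 0.123), and 2 and 1 genes of the list then rose. Of 13 insulin and FOXO responsive genes 4 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.00209, adjusted p = 0.568 with an estimated correlation), and the median was -0.05 where the test pointed up. Those that rose were IGFBP2, IGFBP5, IGFBP3 and TXNIP, with log2 fold changes of 2.03, 2.52, 2.18 and 2.54, and those that fell were IRS1, IRS2 and CITED2. These 3 did not pass after median ratio scaling (adjusted p = 0.225, 0.0699 and 0.324), where 5 genes rose and 0 fell. Without 2D library 2 TXNIP and IGFBP3 did not pass (adjusted p = 0.114 and 0.0882), nor did IGFBP3 without 2D library 1 (adjusted p = 0.0616). IRS1 and CITED2 did not pass without 2D library 1 (adjusted p = 0.142 and 0.416) or 2D library 2 (adjusted p = 0.134 and 0.292). Of 8 drug efflux and ABC transporter genes 3 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00209, adjusted p = 0.729 with an estimated correlation). The list did not pass with no filter (adjusted p = 0.12). ABCA3, a lipid transporter of lamellar bodies, went from 0.56 ± 0.12 to 3.46 ± 0.551 RPKM. ABCA2 and ABCC3 also rose but lost their calls without 2D library 1 (adjusted p = 0.159 and 0.219). ABCC4 fell but lost its call without 2D library 1 or 2D library 2 (adjusted p = 0.0744 and 0.0669). ABCB1 was listed at 0 in all 4 libraries.

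**Figure D2:**
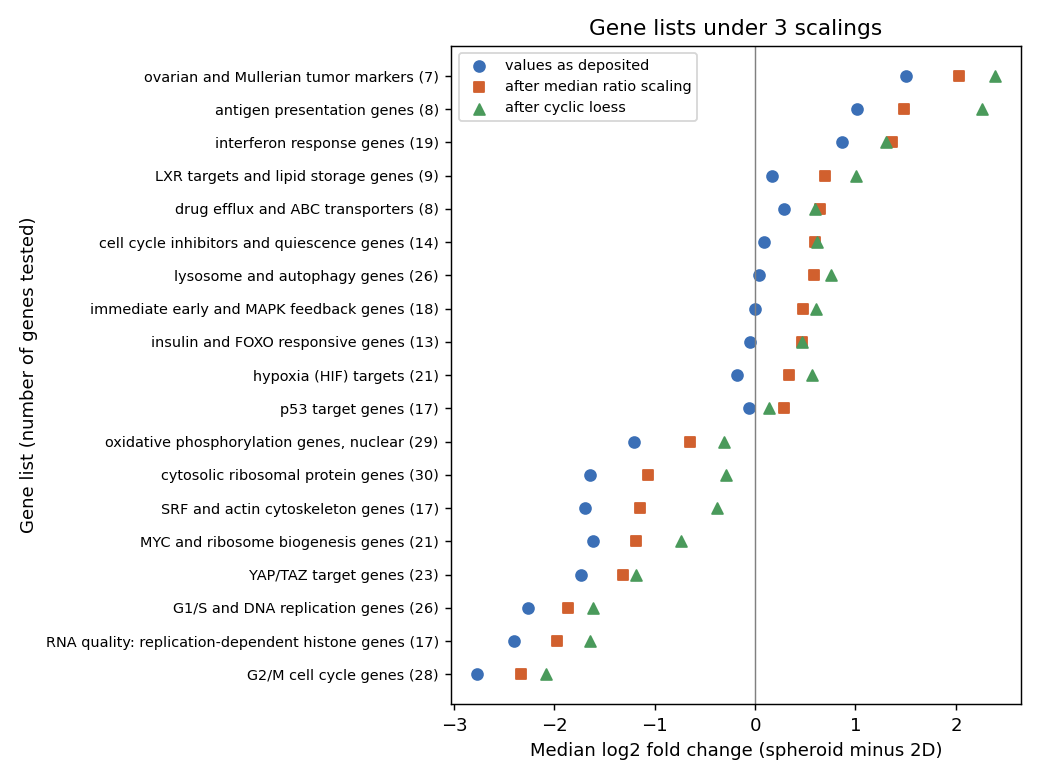
Median log2 fold change (spheroid minus 2D) of the tested genes of the 19 lists past the camera threshold, with values as deposited (circles), after median ratio scaling (squares) and after cyclic loess (triangles). G2/M genes lie lowest at -2.77 as deposited, and ovarian tumour markers highest at 1.51; 11 lists pointed up and 8 down.

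The stem cell and Wnt lists did not pass in the main fit. With the replicate number as a block, the stem cell list passed as lower (camera adjusted p = 0.0393). Of 9 tested stem cell and pluripotency markers 6 fell and 0 rose, the same adjusted over the list alone, and 3 fell after median ratio scaling (camera adjusted p = 0.0958, adjusted p = 0.729 with an estimated correlation). Without 2D library 1 the list passed as lower (adjusted p = 0.0253), and without 2D library 1 or 2D library 2, 3 and 2 genes fell. After cyclic loess 1 rose and 2 fell. ALDH1A3 fell from 3.62 ± 0.254 to 0.417 ± 0.353 RPKM and ITGA6 from 24.9 ± 4.93 to 8.61 ± 2.61. ITGA6 lost its call after cyclic loess (log2 fold change -0.46, adjusted p = 0.105) and without 2D library 1 or 2D library 2 (adjusted p = 0.212 and 0.0898). ID3 fell by 1.23 as deposited and did not pass after median ratio scaling (log2 fold change -0.74, adjusted p = 0.176) or without 2D library 2 (adjusted p = 0.18). MYC fell from 12.6 ± 1.38 to 0.644 ± 0.291 RPKM (log2 fold change -3.05, SE 0.23, adjusted p = 0.000584). CD44, a hyaluronan receptor, had 64.7 ± 6.74 and 65.4 ± 32.7 RPKM, with a log2 fold change of -0.07 (SE 0.43, adjusted p = 0.897). It turned to 0.50 after median ratio scaling (adjusted p = 0.212), 0.74 after rescaling to a fixed sum (adjusted p = 0.0913), and 1.101 and 1.26 after quantile normalization and cyclic loess (adjusted p = 0.0331 and 0.016). Without spheroid library 1 CD44 passed as lower (log2 fold change -0.60, adjusted p = 0.0251).

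Of 12 Wnt/beta-catenin targets 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.11, adjusted p = 0.729 with an estimated correlation). Without spheroid library 1 the list passed as higher (adjusted p = 0.0469), though its median with all libraries was -0.07. Without 2D library 1 the counts were 1 and 1, without 2D library 2 they were 2 and 1, and after median ratio scaling and after cyclic loess 3 and 2. SOX4 rose from 7.9 ± 0.267 to 34.6 ± 3.95 RPKM, MMP7 rose with values of 1.65 and 6.89 RPKM in the spheroid libraries, and JUN fell from 40.2 ± 1.56 to 11.3 ± 3.92. SOX4 and JUN lost their calls without 2D library 1 (adjusted p = 0.0712 and 0.0859) and without 2D library 2 (adjusted p = 0.0555 and 0.0913). MMP7 lost its call with no filter (adjusted p = 0.0564) and after quantile normalization, where the fold change was larger (2.50 against 2.085 as deposited, adjusted p = 0.0557). AXIN2 rose from 0.499 ± 0.202 to 1.88 ± 0.817 RPKM (log2 fold change 0.92, SE 0.27, adjusted p = 0.0313). The call was lost after cyclic loess, where the fold change was larger (1.02, adjusted p = 0.0703), and without 2D library 1 (0.78, adjusted p = 0.112) or spheroid library 2 (0.63, adjusted p = 0.0593). Among 4 tested secreted Wnt inhibitors DKK1 (chromosome 10, 54074041 to 54077417) fell from 11.3 ± 0.989 to 0.064 ± 0.091 RPKM (log2 fold change -3.53, SE 0.20, adjusted p = 0.000371, and -3.25 after median ratio scaling). DKK3 fell from 21.5 ± 2.93 to 8.23 ± 1.95. Adjusted over the list alone, the same 2 passed. DKK3 lost its call after cyclic loess (log2 fold change -0.34, adjusted p = 0.199) and without 2D library 1 or 2D library 2 (adjusted p = 0.15 and 0.223).

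Epithelial and mesenchymal genes moved both ways. Of 13 epithelial genes 3 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.826, adjusted p = 0.982 with an estimated correlation), with a median of -0.83 where the test pointed up. After median ratio scaling 3 rose and 5 fell, after cyclic loess 3 rose and 1 fell, and the counts were 1 and 1 without 2D library 1 and 3 and 2 without 2D library 2. KRT7, a keratin, fell from 23.2 ± 2.06 to 0.697 ± 0.071 RPKM and PKP3 from 4.90 ± 0.783 to 1.87 ± 0.21. The junction genes CLDN4 and JUP rose by log2 values of 1.54 and 1.24. CDH1, which codes for E-cadherin, had 0.207 ± 0.107 and 0.263 ± 0.103 RPKM. PKP3 did not pass after median ratio scaling (log2 fold change -0.59, adjusted p = 0.0825) or without 2D library 1 or 2D library 2 (adjusted p = 0.0547 and 0.121). JUP did not pass without 2D library 1 (adjusted p = 0.125). Of 15 mesenchymal genes 3 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.349, adjusted p = 0.935 with an estimated correlation). After cyclic loess 6 rose and 3 fell, and the counts were 2 and 3 without 2D library 1 and 1 and 4 without 2D library 2. SNAI2 fell from 8.89 ± 1.41 to 1.59 ± 0.839 RPKM, and MMP2 and SPARC rose from 2.15 ± 1.22 to 11.6 ± 2.39 and from 1.79 ± 0.743 to 7.37 ± 2.58. SPARC lost its call without 2D library 2 (adjusted p = 0.0741). VIM fell from 441 ± 60.9 to 159 ± 16.7 RPKM (adjusted p = 0.0109), with a log2 fold change of -1.46 as deposited and 0.02 after cyclic loess. VIM did not pass without 2D library 1 or 2D library 2 (adjusted p = 0.304 and 0.181). FN1 had 96.2 RPKM in 2D and 963 and 103 RPKM in the spheroid libraries and did not pass (log2 fold change 1.72, adjusted p = 0.147). It passed after cyclic loess (3.20, adjusted p = 0.0422) and without spheroid library 2 (3.33, adjusted p = 0.003), and had 0.12 without spheroid library 1 (adjusted p = 0.682).

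ERBB2 (chromosome 17, 37856231 to 37884915), the receptor gene amplified in some breast and ovarian cancers, rose with a log2 fold change of 2.02 (SE 0.33, adjusted p = 0.00519), and 2.60 after median ratio scaling. The log2 fold change was 1.89 without 2D library 1 and 2.15 without 2D library 2. The call was lost in both of these fits, whose spread rests on the spheroid libraries alone.

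Of the 42 lists 19 passed the camera threshold, and with an estimated correlation 0 did, the lowest adjusted p being 0.568. The latter test rests on 2 residual degrees of freedom and cannot decide against a list. Medians as deposited were ranked against random lists matched on expression, which ignore correlation between genes. The percentile was 0 for G2/M, G1/S and YAP/TAZ genes, 0.58 for ribosomal protein genes and 100 for interferon, antigen and ovarian genes. Among lists that did not pass it was 0.39 for TGF-beta and 7.47 for stem cell genes. For epithelial genes, where camera pointed up, it was 11.28, for mesenchymal genes 85.67 and for Wnt targets 95.11. The fry test, which asks whether the genes of a list move 1 way on balance and does not set them against other genes, called 10 lists. Of these 4 were among the 19 (interferon response, ovarian tumour, ribosomal protein and YAP/TAZ genes) and 6 were not (stem cell, Notch, TGF-beta and BMP, glycolysis, ATF4 and ERBB genes). The G2/M and G1/S lists had adjusted p of 0.0708 and 0.0935 by fry. As fry tests against no change, the shift of all genes enters it. After median ratio scaling it called 13 lists, 7 of them among the 10. Notch, glycolysis and ATF4 genes then did not pass (adjusted p = 0.489, 0.113 and 0.0751), while epithelial, SRF, LXR, antigen presentation, insulin and MYC genes did (adjusted p = 0.0324, 0.0447, 0.0129, 0.0318, 0.047 and 0.0447). The 7 that passed beyond the 12 above were LXR targets and lipid storage (3 rose, 1 fell of 9), hypoxia targets (4 and 4 of 21), SRF and actin genes (0 and 14 of 17), immediate early and MAPK feedback genes (4 and 4 of 18), p53 targets (3 and 2 of 17), cell cycle inhibitors and quiescence genes (3 and 4 of 14) and nuclear genes of oxidative phosphorylation (0 and 19 of 29). In that order the counts after median ratio scaling were 3 and 0, 5 and 2, 0 and 12, 8 and 3, 6 and 1, 6 and 2, and 0 and 8. After cyclic loess they were 4 and 0, 8 and 1, 2 and 5, 8 and 3, 5 and 1, 6 and 1, and 1 and 2. Without 2D library 1 they were 2 and 0, 3 and 0, 0 and 3, 3 and 2, 2 and 1, 3 and 1, and 0 and 2. Without 2D library 2 they were 2 and 0, 3 and 1, 0 and 4, 2 and 2, 2 and 1, 3 and 1, and 0 and 5. Without spheroid library 1 they were 4 and 3, 7 and 5, 0 and 15, 5 and 7, 3 and 6, 3 and 4, and 0 and 27, and without spheroid library 2 they were 3 and 1, 5 and 6, 0 and 14, 6 and 4, 4 and 3, 4 and 2, and 0 and 22. The camera adjusted p of these 7 lists lay between 0.00297 and 0.0188. The hypoxia, immediate early and p53 lists had medians of -0.185, -0.006 and -0.063 where the test pointed up. Immediate early genes did not pass after median ratio scaling (adjusted p = 0.0556). They, p53 targets, cell cycle inhibitors and oxidative phosphorylation genes did not pass after cyclic loess (adjusted p = 0.0581, 0.0969, 0.0635 and 0.118) or without 2D library 2 (adjusted p = 0.0864, 0.0864, 0.0777 and 0.137). Oxidative phosphorylation genes also did not pass without 2D library 1 (adjusted p = 0.0896). The same holds for immediate early genes without spheroid library 1 (adjusted p = 0.066) and hypoxia targets without spheroid library 2 (adjusted p = 0.148). With no filter the hypoxia, immediate early, p53 and cell cycle inhibitor lists did not pass (adjusted p = 0.29, 0.205, 0.342 and 0.166). Of extracellular matrix genes 4 of 22 rose and 9 fell, of the ERBB family and ligands 2 of 7 rose and 4 fell, and of TGF-beta and BMP targets 0 of 16 rose and 10 fell. After cyclic loess these counts were 7 and 5, 2 and 3, and 1 and 5. They were 3 and 4, 1 and 3, and 0 and 7 without 2D library 1, and 3 and 7, 1 and 3, and 0 and 6 without 2D library 2. The matrix list (camera adjusted p = 0.511), whose median was -0.626 where the test pointed up, passed as higher than other genes with a minimum of 5 RPKM (adjusted p = 0.0132). The TGF-beta list (camera adjusted p = 0.229) passed as lower without 2D library 1 (adjusted p = 0.00506) and without 2D library 2 (adjusted p = 0.0111).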

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

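The rule for this part was chosen after the data were seen. Below the filter of 1 RPKM, where no test was run, 27 genes had no read in either 2D library and at least 10 reads in each spheroid library, and 11 genes had the reverse. Among the 27, IFI44L had 82 and 112 reads, COL3A1 53 and 141, CIITA, the regulator of class II antigen presentation, 20 and 26, PECAM1 75 and 30, PTPRC 17 and 31, VCAM1 25 and 24, and CLDN10 26 and 38. Against 3 reads over both 2D libraries, IFI44L was at least 62.3-fold higher and COL3A1 at least 60.1-fold. Among the 11 that had reads only in 2D were DOCK2 with 71 and 143 reads and TENM2 with 60 and 50.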

How the results depend on the processing

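Cyclic loess, voom on recovered reads and the median ratio fits with a library left out were chosen after the data were seen. Genes higher in spheroids (643) numbered 167 with a minimum of 5 RPKM, 1366 after median ratio scaling, 1250 after quantile normalization, 1911 after rescaling to a fixed sum, 1504 after cyclic loess and 1883 by voom; genes lower (4198) numbered 2524 with no filter, and 2134, 1306, 1323, 1444 and 2070 in the last 5. At 2-fold or more the higher genes (381) numbered 127 with a minimum of 5 RPKM, and 753, 794, 1486, 857 and 1366 in those 5, and the lower genes (2898) 1154, 792, 952, 780 and 1287. With 1 library left out, the counts ranged from 4 to 2242 higher and 23 to 6574 lower, and at 2-fold or more from 4 to 1092 and from 23 to 4051 (from 269 to 419 and from 1206 to 4051 with values as deposited). Median ratio scaling gave 4 and 23 without 2D library 1, 9 and 47 without 2D library 2, 2242 and 3414 without spheroid library 1 and 1384 and 2238 without spheroid library 2; a lone library is assumed to vary like the other group. No gene called in one direction as deposited was called in the other under an alternative (0 genes). With the replicate number as a replicate block 869 were higher and 5019 lower, and the stem cell, TGF-beta and heat shock lists passed as lower (adjusted p = 0.0393, 0.0107 and 0.0377). The heat shock list (0.0543) also passed with no filter (0.00819), after median ratio scaling (0.0159), rescaling (0.00983) and voom (0.00818), with no trend in the empirical Bayes step (0.0297), and without spheroid library 1 or 2 (0.00792 and 0.0307). The libraries share only a number, and deviations of same-numbered libraries correlated across genes at 0.114. Of the list tests 0 passed with an estimated correlation, the other alternatives of camera gave 13 to 22, and fry, which tests against no change, called 10. The direction of the camera test of the epithelial list, up as deposited although its mean lay -0.076 from that of other genes, turned down, with mean differences of -1.02 with a minimum of 5 RPKM, -0.077 after median ratio scaling, -0.036 after quantile normalization, -0.036 after rescaling, -0.034 after cyclic loess and -0.04 by voom, and differences from -0.154 to 0.002 with 1 library left out; the mesenchymal list (0.124) ranged from -0.067 to 0.314, and its test turned down without 2D library 2 (-0.034). CD44 turned to 0.50, 1.101, 0.74, 1.26 and 0.61 after median ratio scaling, quantile normalization, rescaling, cyclic loess and voom, and ranged from -0.598 to 0.451 with 1 library left out; VIM turned to 0.022 after cyclic loess. The cause was not tested. Among the alternatives fixed before the data were examined, 1178 of 1251 comparisons of named genes kept direction and side of the threshold, 67 lost the call, 1 gained it and 5 changed sign. Depth of 7.98 M to 11.08 M reads limits genes near 1 RPKM.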

Other observations

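The tests of leukocyte markers (their median and the reads per cell type), of the scale of the spheroid libraries and of a trend with expression level, the count of olfactory receptor genes with a read, and the windows around ERBB2 were chosen only after the result was seen. In a block around ERBB2 on chromosome 17 most tested neighbours also rose. From PPP1R1B to GSDMB 10 genes were tested, counting ERBB2 itself and MIR4728. Of these 9 passed as deposited and 10 after median ratio scaling and after cyclic loess. The ends of the block were not fixed before the values were seen, and PPP1R1B was already among the 10 largest rises. The count within these ends therefore describes the block and is not a test of it. ERBB2 and MIR4728 overlap in position and may not be independent. STARD3 had a log2 fold change of 2.01, TCAP 2.00, PNMT 1.70, PGAP3 1.38, MIR4728, which lies within ERBB2, 3.37, GRB7 1.99 and GSDMB 1.39, while MIEN1 had 0.50 as deposited (adjusted p = 0.227) and 1.07 after median ratio scaling. On the flanks, MED1, CDK12 and PSMD3 had -1.05, -0.46 and -1.51. In windows of 7 tested neighbours in genome order, the one centred on PNMT had the highest median of 11128 windows after cyclic loess (3.12), and with windows of 5, 9 and 11 genes 33, 22 and 22 windows were higher. Overlapping rows of the protocadherin gamma cluster, which share exons, were among the highest windows and are not independent. No explanation of this block was tested.

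In the ERBB family list, EGFR fell from 21.7 ± 1.89 to 3.42 and 2.57 RPKM and its relative's ligand NRG1 from 16.6 ± 0.316 to 1.03 and 0.961, while ERBB2 rose. COL6A2 rose with COL6A1, from 8.22 ± 0.014 to 54.5 and 89.7 RPKM. Of 21 hypoxia targets 4 rose and 4 fell as deposited, 5 and 2 after median ratio scaling and 8 and 1 after cyclic loess. VEGFA, CA9, CA12 and ANGPTL4 rose, VEGFA from 18.4 ± 0.23 to 47.0 and 159 RPKM and CA9 from 0.711 ± 0.26 to 2.61 and 11.6, while BNIP3, EGLN1, ERO1L and PFKFB3 fell by 1.42, 1.23, 1.02 and 0.93 on the log2 scale. VEGFA, BNIP3, ERO1L and PFKFB3 lost their calls without 2D library 1 (adjusted p = 0.075, 0.156, 0.465 and 0.288) and without 2D library 2 (adjusted p = 0.064, 0.0991, 0.254 and 0.297), EGLN1 without 2D library 1 (adjusted p = 0.0889), and CA9 after cyclic loess (adjusted p = 0.0592). These genes were chosen after their values were seen.

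The spheroid libraries had a lower share of reads in sense exons. Opposite-strand genes had median ratios of 0.015 and 0.026 in the spheroid libraries to the gene whose exons they cover. In the 2D libraries these were 0.0121 and 0.0146. The low ratios argue against loss of strand information as the main cause. For loss of 5' coverage, fold change would fall with exon length, and it rose (Spearman rho 0.134 across genes). However, fold change also fell with mean level (Spearman rho -0.448). Level was not held constant, so the test by length cannot decide on 5' coverage. For genomic DNA, the test set before the result was seen was the sum of reads on 377 olfactory receptor genes. It came out in favour of genomic DNA, with 1.457 times the 192.2 reads expected from the missing exon share. That ratio took all spheroid reads (120 and 160) without taking off those also present in 2D (58 and 101). It therefore overstates the excess in spheroids. However, 360 of the 439 reads of the 4 libraries lay on 10 of the genes, and 21 and 23 of the genes had a read in the spheroid libraries against 23 and 22 in 2D, at most 0.36 of the number an even spread would give, which argues against DNA spread over the genome, though this second count was chosen after the first was seen. For more unspliced RNA, reads on microRNA rows inside introns per read in host exons were 2.2 times higher in spheroids (95% exact interval 1.86 to 2.6, counting error only). This met the bound set for that explanation. However, host exon reads fall with the exon share itself, so the ratio would rise even with intronic reads unchanged. The intronic reads were 114 and 147 in 2D and 146 and 174 in spheroids, at depths of 7.98 M, 11.08 M, 8.71 M and 10.97 M. The ratio therefore cannot decide on more unspliced RNA. A change in nuclear RNA of the spheroid cells, the biological form of the same explanation, also stays open.

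The rise of interferon response and antigen presentation genes is set against 3 explanations. The first, leukocytes in the spheroid samples, would need cells beyond the SKOV3 line, the only cells named in the sample titles. The median of the 15 leukocyte markers was 0.0 RPKM in the higher spheroid library and in the other libraries, a floor that says little over mixed cell types, while PTPRC (0 reads in 2D, 17 and 31 in spheroids), CD52, a lymphocyte antigen outside the list (0 and 1 reads, then 65 and 51), and CD68 after median ratio scaling (log2 fold change 0.78, adjusted p = 0.0485) went with leukocytes. Against the reads expected had each marker gained as many RPKM as the median of the 27 genes (1.74 and 2.41), spheroids had 0.235 on PTPRC, 0.017 on 6 myeloid markers, LYZ and TYROBP among them, 0.004 on 4 of T and NK cells and 0.0 on 2 of B cells (95% upper limits 0.311, 0.032, 0.022 and 0.017, counting error only), which argues against leukocytes of these types as the whole source and leaves a small share open. After cyclic loess, which removes the trend with expression level, the median of the 27 genes was 1.42 (bootstrap SD 0.34), and in the lower of the spheroid libraries after median ratio scaling it was 1.22 (bootstrap SD 0.24), so that neither that trend nor 1 library accounts for it as a whole. A response of the tumour cells to spheroid culture, its medium or its plate may be involved, and the design changes these together.

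Spheroid library 2 lay farther from the 2D libraries than spheroid library 1. Its root mean square change was 1.28 times that of library 1 as deposited, or 1.45 with the 2D libraries exchanged, and 1.16 or 1.35 after median ratio scaling, so that a different scale of the libraries is argued against as the whole cause (bootstrap SD over genes at most 0.012). The changes of both libraries, each against a different 2D library, correlated at 0.78 across genes after cyclic loess, or 0.77 with the 2D libraries exchanged, and the SD ratio was 1.14 or 1.29. Library 2 may show much the same change at a larger size, which depends on the choice of 2D library. No biological explanation was tested.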
